A study of Danio rerio with 2 samples.

How the data were processed

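The series measured binding of the transcription factor Prdm1 (Blimp-1) in zebrafish muscle cells by chromatin immunoprecipitation and hybridisation to promoter tiling arrays. Per the labels' protocols, embryos were injected with a dominant negative form of protein kinase A, which raises hedgehog signalling and Prdm1 levels, and were grown to between 12 and 14 somites. Cells with an alpha actin GFP reporter were sorted, and triplicates of sorted cells were used for immunoprecipitation. Immunoprecipitated chromatin and whole cell extract were labelled with different dyes and hybridised together, so each array carried its own control. Per the series' design text, 352490 probes of 60 nt were divided between 2 slides and covered 9 kb before and 3 kb after the transcription start of 11512 genes, with coordinates in the Zv6 assembly. Slide 1 held mainly chromosomes 1 to 12 and slide 2 mainly chromosomes 13 to 25 and unplaced contigs, with some probes on both, and 196 gene names occurred on both slides. Each slide design was hybridised on 3 arrays. The labels do not say whether the 3 arrays came from separate cell preparations or from repeats of the same one, so p-values measure only the spread between these arrays, which may be technical.

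The deposited spot values are intensity values of each channel, written by Agilent Feature Extraction 9.1.3.1, per the file headers. That program subtracted background, removed spatial trends, multiplied each channel by a linear dye factor and put a surrogate value where a spot was not above background. The same deposited files give a log10 ratio of red (Cy5) over green (Cy3), which was exactly 0 for between 84.8% and 90.6% of the non-control spots of an array because both channels held surrogates. A deposited value table, with no scale, centring or direction stated by the authors, held values close to a log2 ratio of Cy5 over Cy3 combined over the arrays of a slide. Against the scanner ratios its slope was 0.972 on slide 1 and 0.989 on slide 2, with Pearson correlations of 0.936 and 0.963 across spots. Its medians were -0.08 and -0.06, and 29155 and 25232 of its values were empty. Its centring stays unknown, as does the way arrays were combined.

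Channel labels place the immunoprecipitate in Cy5 and the whole cell extract in Cy3, and the treatment protocol states the opposite. Ratios were therefore written as Cy5 over Cy3, "higher" and "lower" refer to Cy5, and the turned sign was run as an alternative.

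Processed signals were turned into log2(Cy5/Cy3) and centred on the median of each array, with no further scaling. Control spots were left out, as were spots with an outlier flag on any array (8265 on slide 1 and 4434 on slide 2). A probe had to be well above background in at least 1 channel on every array. Few spots passed. Depth, as the percentage of non-control spots above background in either channel, was 13.4%, 13.9% and 16.1% for replicates 1, 2 and 3 of slide 1 and 13.5%, 12.8% and 9.40% for slide 2. On slide 1, 15745 of 173173 spots were used (9.09%), and on slide 2, 12796 of 174270 (7.34%). The median GC content was 45% for used probes and 35% for the others. The number of arrays limits the precision of every ratio.

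Windows held a probe and its nearest neighbour on each side within 1000 bp, with at least 2 probes, so an isolated pair of probes gives 2 windows with the same value. Window means of the 3 arrays of a slide were tested against 0 with limma 3.58.1 (lmFit with an intercept and eBayes, two-sided) in R 4.3.3, with data.table (version 1.17.8), and p-values were adjusted by Benjamini-Hochberg within a slide. The eBayes step draws the variance of each window toward that of all windows of the slide, so a p-value does not rest on its own 3 values alone. A window was called at an adjusted p under 0.05 and a change of at least 2-fold, and called windows within 1000 bp were merged into regions. A gene was called when its name stood on the centre probe of a called higher window. Simulated data used the real positions of each slide and independent normal noise, with the real probe spreads shuffled over positions. All 50 sites raised equally on the 3 arrays were called at each log2 size of 1.5, 2 and 3. With a mean log2 of 2 divided unequally between the arrays, 0 of 50 sites were called. No window without an effect was called (0 of 6405 on slide 1 and 0 of 4473 on slide 2). On the real slides the ratios of neighbouring probes correlated (r = 0.32 on both), so this does not bound the false calls there.

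Gene names were those of the array files, and 28.8% and 27.7% of the spots carried coordinates only. Of 10782 names, 5859 matched a symbol or synonym in the RefSeq gene table of the GRCz12tu assembly, which was used for names alone. The other 4923 names, of which 3775 begin with ENSDART and 826 with OTTDART, were kept as written. No Zv6 genome, start sites or gene models were used here, so positions relative to start sites, exons or introns were not analysed, and neither was the planned restriction to windows near them.

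The gene lists tested were: fast muscle contractile, slow muscle contractile, myogenic regulators, hedgehog pathway, duplicated design genes, B cell Prdm1 targets, neural crest and sensory neuron, somite segmentation, notochord and axial, neural, blood and vessel, epidermis, and housekeeping. Each was tested by Fisher's exact test (two-sided) of called genes against all other genes with a window, adjusted over the lists. Each list's median best window per gene was also placed among 10000 random lists of equal size matched on windows per gene. Counts adjusted over the list alone used the limma p-values of the list's own windows. These lists, the test, the alternatives and the naming rule were fixed before the data were examined. The rule named the 25 called genes with the highest best window that were positive on every array, up to 6 members per list, the duplicated design genes, prdm1 and sox6. A member of the myogenic regulators that the rule names is not reported here.

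Alternatives changed the signal, normalisation, centring, probe filters, window, thresholds, test, adjustment, replicates and sign. A second way of reading the arrays was added after the first result was seen and is called the all-probe reading below. It used mean minus local background signals (floor 1, offset 20), loess within each array (span 0.3), no filter on dim probes, and a rule without a test that a window differ by at least 1.5-fold in the same direction on every array. Probe sequences were searched for the Prdm1 consensus binding sequence with up to 50 GC-matched probes per called probe and 100 shuffled motifs. Translated probes were matched (70% identity over 15 residues) to sequences of conserved muscle and housekeeping proteins that were entered by hand and not taken from a database, in Python 3.11.15, and copies between probes (80% identity over 40 nt) were found with BLAST 2.17.0. Figures were drawn with matplotlib 3.10.9.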

Results

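The arrays addressed which promoters Prdm1 occupied in the muscle cells of zebrafish embryos whose hedgehog signalling had been raised. Prdm1 is a zinc finger transcription factor required for the slow muscle fibre fate. Sorted GFP-positive muscle cells from embryos of between 12 and 14 somites gave immunoprecipitated chromatin and whole cell extract, which were compared on the same array. The 3 replicate arrays of slide 1 and the 3 of slide 2 held mostly different promoters, and the single comparison was the ratio of the channels. All ratios are log2 of Cy5 over Cy3, given as mean ± SD over 3 arrays. The channel labels name Cy5 as the immunoprecipitate and the treatment protocol names Cy3, so which sign stands for binding was not settled. Between 9.40% and 16.1% of the probes on an array were brighter than background. After filtering, 13115 windows of neighbouring probes near 2694 named genes could be tested.

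Among the tested windows, the highest ratios lay in a cluster of myosin heavy chain genes on chromosome 5. Near myhz2, which encodes a fast skeletal myosin heavy chain, the best window (Zv6 chromosome 5, 30198664 to 30198740) had a log2 ratio of 1.69 ± 1.51 on slide 2 (n = 3), and the arrays gave 0.89, 0.75 and 3.44. The same window printed on slide 1 had 1.57 ± 1.76. All 17 windows with a mean at least 2-fold higher in Cy5 lay on chromosome 5 between 30198664 and 30337474. Of these, 12 were named myhz2, 1 was named zgc:113832 (RefSeq myh7l, a myosin heavy chain), 1 was named ENSDART00000019132.41 and 3 had no gene name. The zgc:113832 and ENSDART00000019132.41 window (30336574 to 30337474) had a log2 ratio of 1.26 ± 1.25. In the other direction, 2 windows on slide 2 had a mean at least 2-fold lower.

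With limma, 0 windows passed the threshold of adjusted p and 2-fold change in either direction. The best myhz2 window had adjusted p = 0.101 on slide 2 and 0.0825 on slide 1. At an unadjusted p under 0.05, 869 windows were higher and 1796 lower. Without the 2-fold requirement, 26 windows were higher at 15 genes and 118 were lower. Without replicate 1, 20 windows were called higher and 27 lower, and without replicate 3, 0 were higher and 4 lower. Single probes, which lack the averaging over neighbours, gave 29 higher and 18 lower calls.

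**Figure D1:**
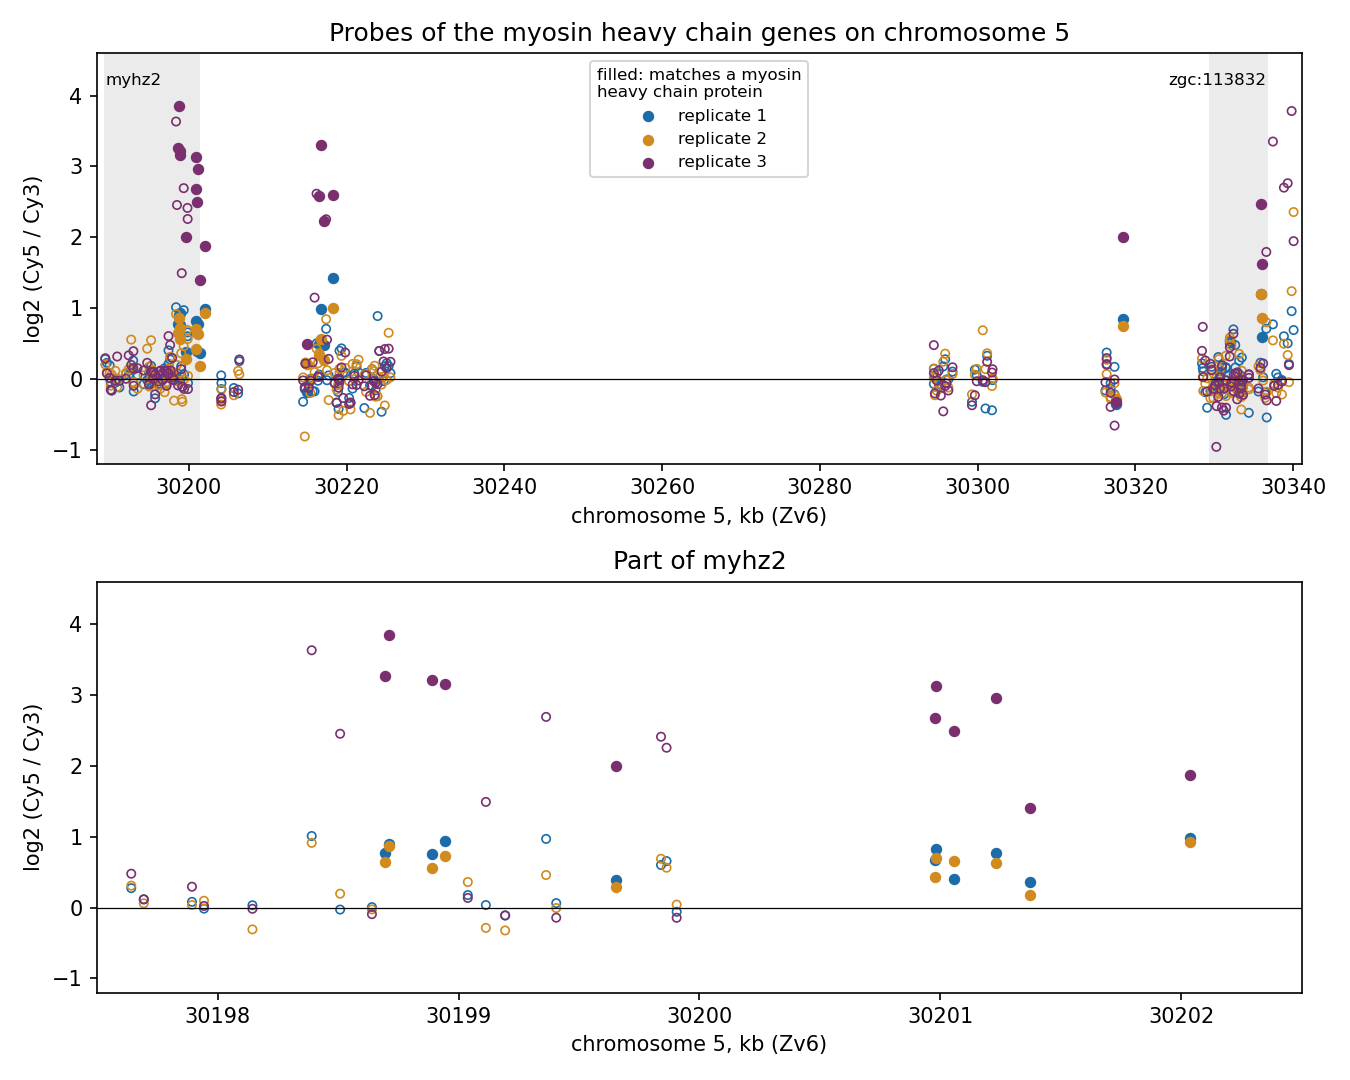
Log2 ratio of Cy5 over Cy3 in the all-probe reading (vertical axes) against position in kb on Zv6 chromosome 5 (horizontal axes) across the myosin heavy chain cluster from 30189391 to 30340095 (top, with the probes named myhz2 and zgc:113832 shaded) and in part of myhz2 (bottom), with each point 1 probe on 1 array coloured by replicate. The 20 probes whose translation matches a skeletal myosin heavy chain (filled) had a median of 1.26 and the other 183 (open) of 0.02, with the highest values on replicate 3.

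The highest windows that passed the adjusted p without a 2-fold change were at rgs6, a regulator of G protein signalling (0.68 ± 0.15, chromosome 20, 44459791 to 44460652, adjusted p = 0.0409), and ube3c, a ubiquitin ligase (0.68 ± 0.17, chromosome 7, 48716104 to 48716414, adjusted p = 0.0237). They were followed by the homeobox genes mxtx1 (0.63 ± 0.12) and hoxb2a (0.63 ± 0.03, chromosome 3, 22957263 to 22958046). The mitotic kinase gene plk1 had 0.48 ± 0.03, the Polycomb group ubiquitin ligase gene rnf2 had 0.47 ± 0.14, and eif2b3, which encodes a subunit of a translation initiation factor, had 0.50 ± 0.15. Each of these was higher on 3 of 3 arrays. The rgs6, ube3c and hoxb2a windows held 2 probes each and rested mainly on 1 of them. Alone, that probe had 1.21 ± 0.16, 1.34 ± 0.24 and 1.08 ± 0.02, so its neighbour lay well below the window mean. In the hoxb2a window the high probe (22957987 to 22958046) carried no gene name, and the probe named hoxb2a was the lower neighbour. With loess within arrays and no fold requirement, ube3c and hoxb2a passed and the other genes named here did not.

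Lower windows at this level had a median log2 ratio of -0.53 on slide 1. Of the 113 on slide 1, 62 lay on chromosome 4, where 1159 of the slide's 7545 windows were tested. On chromosome 3 there were 22, of 873 tested. Many of these windows overlapped or held the same probes, so they are not separate sites. The lowest was at OTTDART00000014145 on slide 2 (-0.91 ± 0.19). It was followed by zgc:64187 (RefSeq gpr39, a G protein-coupled receptor) at -0.85 ± 0.10 with adjusted p = 0.0143, and ttc35 (RefSeq emc2, of the endoplasmic reticulum membrane complex) at -0.81 ± 0.31. The window of zgc:92099 (RefSeq ccdc47) had -0.77 ± 0.33. In the actin gene acta1 (RefSeq actc1b), 1 window (chromosome 1, 63893971 to 63894280) had -0.71 ± 0.19 with adjusted p = 0.0237, and the gata2b window (zgc:91840 in the files) had -0.49 ± 0.09. All were lower on 3 of 3 arrays. With loess within arrays 8 lower windows passed in place of 118, and ttc35 was also among the genes with the strongest bright runs of probes on slide 1. The acta1 window lay within a bright run of that gene's probes (63890204 to 63895897).

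**Figure D2:**
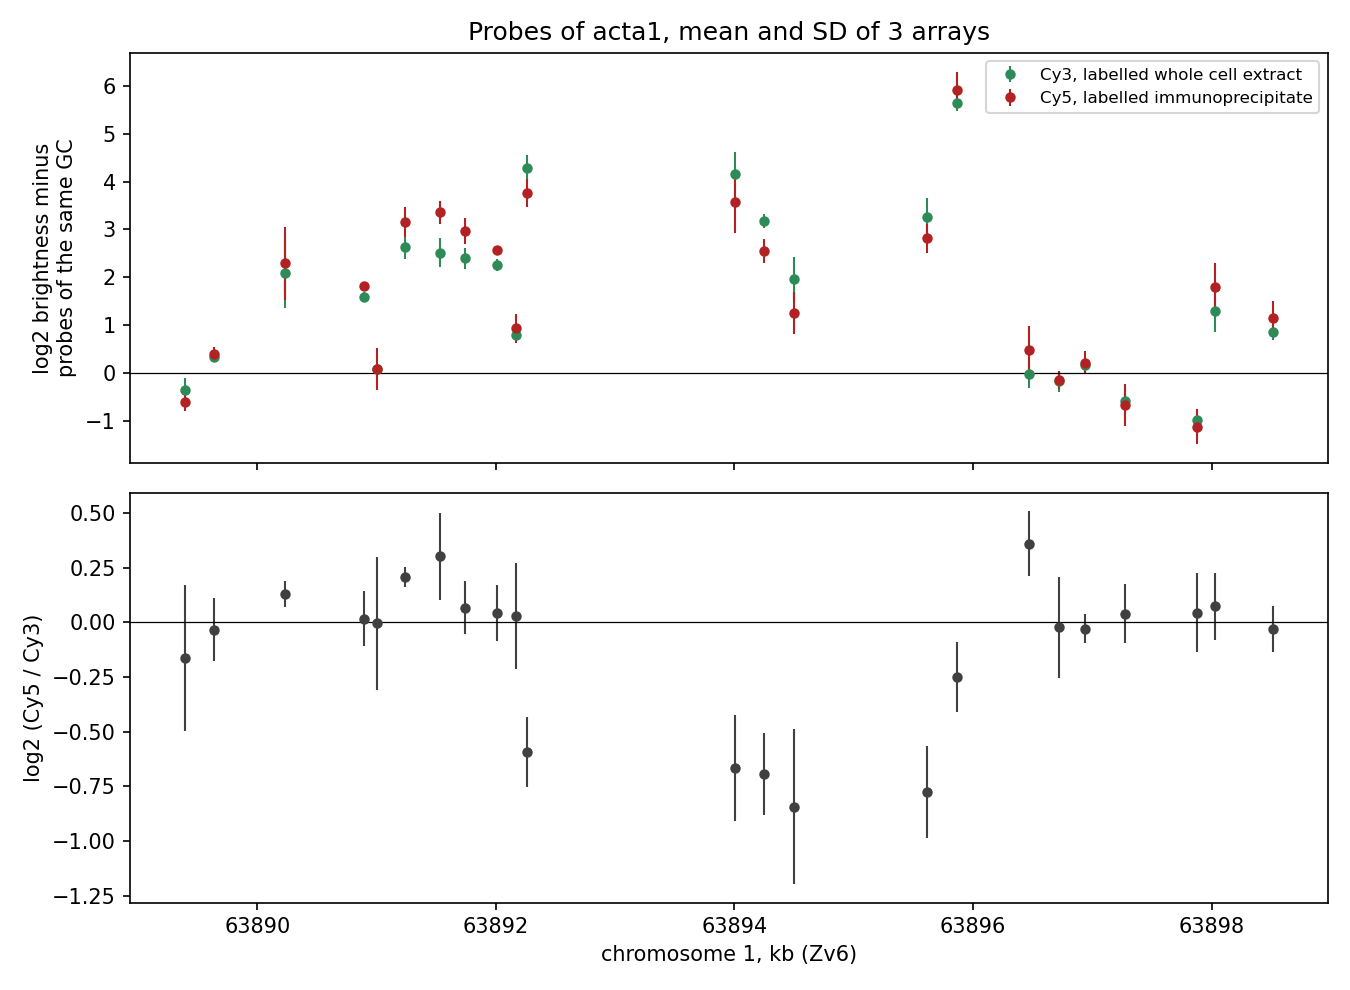
Log2 brightness of acta1 probes above probes of equal GC content in each channel (top) and their log2 ratio of Cy5 over Cy3 in the all-probe reading (bottom), as mean and SD over 3 arrays, against position in kb on Zv6 chromosome 1. The 14 probes from 63890204 to 63895897 had a median brightness excess of 2.77 and the other 9 of 0.19, and 6 of the 14 had ratios below 0 on every array.

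Among the fast muscle contractile genes, myhz2 stood apart from the other members. Of 30 members on the arrays, 11 had a window and none was called over all windows with limma. Adjusted over the list alone, 12 windows were at least 2-fold higher, all of myhz2. With no fold requirement, 15 were higher and 8 lower. The higher ones included actn3, the alpha actinin of fast fibres (0.36 ± 0.05), and ckm, muscle creatine kinase (0.28 ± 0.03). The lower ones were 4 windows of mylz2, the fast myosin regulatory light chain (down to -0.44 ± 0.26), and 4 of acta1. Those of acta1 lay within its bright run of probes and, like those of actn3, included pairs of windows with the same value. The list's median lay at percentile 87.0 of random lists, but at 28.9 with the sign turned, 40.2 with no filter on dim probes, 98.8 with outlier spots kept and 99.1 as single probes. Best windows of the troponin I gene zgc:92053 (RefSeq tnni2a.3) and of zgc:77785 (RefSeq myoz1a, a Z-disc protein) had 0.16 ± 0.05 and 0.12 ± 0.21 and did not pass.

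Few slow muscle genes had windows. Of 15 slow muscle contractile members on the arrays, 2 had windows, atp2a2a (a calcium pump of the sarcoplasmic reticulum) at 0.07 ± 0.06 and zgc:103458 (RefSeq tnni1b, slow troponin I) at -0.17 ± 0.17. Neither passed over all windows, and a list of that size was not tested. As single probes 11 members were measured and 0 were called with limma, but prox1, a homeobox gene of slow fibres (0.54 ± 0.13, adjusted p = 0.00785), and mb, myoglobin (0.49 ± 0.04, adjusted p = 0.0399), passed the adjusted p below a 2-fold change. The gene sox6, a transcription factor of fast fibre differentiation, carried 0 probes under that name.

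Of 12 myogenic regulators with a window, 0 were called over all windows with limma, while 8 windows were higher when adjusted over the list alone, among them 2 each of smyd1a, eng1a and prdm1, and 0 of the 8 reached 2-fold. The smallest p adjusted over the list alone was 0.0470. Best windows were 0.35 ± 0.23 at smyd1a, which encodes a methyltransferase needed for sarcomere assembly, and 0.31 ± 0.11 at eng1a, a marker of muscle pioneer fibres. At prdm1 itself (chromosome 16, 7750939 to 7751954) the value was 0.29 ± 0.01, with adjusted p = 0.152 over all windows. The list's median lay at percentile 97.6, but at 2.37 with the sign turned, 25.6 with no filter on dim probes and 3.65 in the all-probe reading.

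Axial and neural markers, which belong to cells outside the sort gate, contained values of similar size. In the notochord and axial list, 5 windows were higher when adjusted over the list alone, 3 of the BMP antagonist nog1 (best 0.40 ± 0.17) and 2 of ntl (RefSeq tbxta, best 0.26 ± 0.08), and 0 reached 2-fold. The copa window had 0.15 ± 0.13 and did not pass. This list, with 3 members that had windows, lay at percentile 98.7, but at 0.54 with the sign turned and 44.8 in the all-probe reading. In the neural list, 4 windows were higher when adjusted over the list alone, 2 of pax2a, a midbrain and hindbrain regulator (0.51 ± 0.20), and 2 of the glial filament gene gfap (0.37 ± 0.09). The proneural gene ascl1a had 1 lower window (-0.37 ± 0.27), and the list's percentile was 68.3, but 47.1 with the sign turned and 1.29 in the all-probe reading. In the epidermis list, 2 windows of the keratin gene krt18 were lower when adjusted over the list alone (-0.34 ± 0.14). The best windows of krt8 (0.11 ± 0.14) and krt5 (-0.15 ± 0.13) did not pass. For each of ntl, pax2a, gfap and krt18 the 2 windows had the same value, as 1 pair of probes gives, so they are not separate measurements.

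In the remaining lists 0 windows passed with limma when adjusted over the list alone, except the duplicated design genes. In the hedgehog pathway list the receptor gene ptc1 had 0.21 ± 0.23 and shha had -0.10 ± 0.09. Among B cell Prdm1 targets, junb had 0.24 ± 0.21, myca had 0.01 ± 0.21, and xbp1, a regulator of plasma cell secretion, had -0.04 ± 0.06. Among somite segmentation genes, the Notch ligand gene dla had 0.33 ± 0.26 and lfng had 0.12 ± 0.13. Neural crest and sensory neuron genes included sox10 at 0.18 ± 0.17 and foxd3 at 0.02 ± 0.26. The 10 of 29 members with a window gave percentile 51.1 (57.3 with the sign turned), but with no filter on dim probes all 29 gave 2.22, and in the all-probe reading 0.01. Among blood and vessel genes, the chemokine receptor gene cxcr4b had 0.32 ± 0.01 and gata1 had 0.07 ± 0.16. Housekeeping genes included bactin2 at 0.21 ± 0.05 and ppia at 0.18 ± 0.01. The percentiles of these lists moved with the settings and none is ranked here. That of the hedgehog list was 42.5, with 34.9 when the sign was turned and 90.2 without replicate 3, and that of the housekeeping list was 67.1, with 13.2 when the sign was turned. Fisher's exact test gave p = 1 for every tested list, since 0 genes were called.

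**Figure D3:**
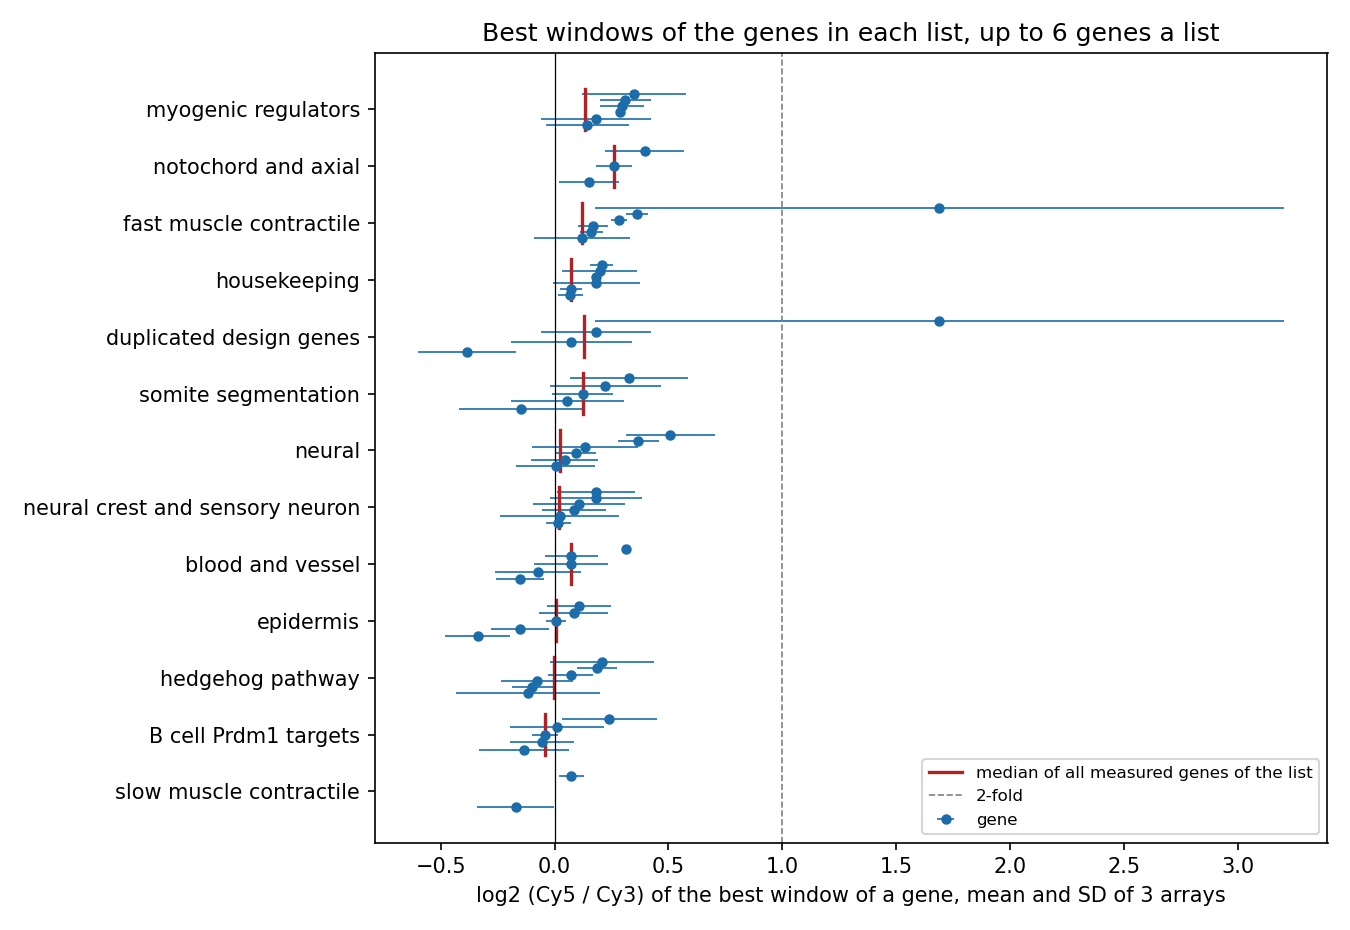
Log2 ratio of Cy5 over Cy3 of the best window of a gene (horizontal axis, mean with SD over 3 arrays), for up to 6 genes with the highest values in each list (vertical axis), with red bars at the list medians and a dashed line at 2-fold. Only myhz2, at 1.69 in both lists that hold it, has a mean beyond the line.

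The duplicated design genes gave a direct comparison between slides. Adjusted over the list alone, 12 windows were at least 2-fold higher, all of myhz2, and 4 windows of mylz2 were lower at less than 2-fold. The list's percentile was 74.6, but 3.26 with the sign turned and 6.96 without replicate 3. The somite gene msgn1 (0.18 ± 0.24) and wnt11 (0.07 ± 0.26) had windows that did not pass, and tnnt3a, flh, vent, myod, fgf8 and pcdh8 had no window. At 26 positions measured on both slides the mean ratios correlated across probes with r = 0.984 and rho = 0.954, and the 11 of these outside chromosome 5 had r = 0.841. In the all-probe reading 326 shared positions had r = 0.938 and rho = 0.786. The mean difference between slides was 0.00 with an SD of 0.11 at the 26 positions and -0.01 with an SD of 0.10 at the 326.

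Single probes were called at 11 genes, and these went beyond muscle. Besides myhz2 (1.81 ± 1.55), ENSDART00000019132.41 and zgc:113832 (1.13 ± 0.74), they included ube3c (1.34 ± 0.24, adjusted p = 2.12e-05), rgs6 (1.21 ± 0.16, adjusted p = 2.48e-10) and zgc:100829 (1.04 ± 0.40). The kinase gene eef2k, whose product slows translation elongation, had 1.28 ± 0.22 (chromosome 12, 10750454 to 10750513, adjusted p = 3.03e-05). The other 4 had transcript names only. The lowest named probe was that of the homeobox gene hoxc6b (-2.48 ± 0.73, chromosome 11, 1378282 to 1378341, adjusted p = 1.92e-07). Among named probes it was followed by zgc:64187 (-1.44 ± 0.34), prss35, a serine protease gene (-1.31 ± 0.23), zgc:92099 (-1.14 ± 0.64), sfxn1, a mitochondrial serine carrier gene (-1.13 ± 0.14), and pou12 (RefSeq pou3f3a, -1.11 ± 0.35). Overlapping probes with no gene name on contig NA695 had -2.43 ± 1.59 and -2.28 ± 1.41 (limma, adjusted p = 6.98e-17 for each). Such p-values depend strongly on the variance that limma pools over a slide, so they are not comparable between slides. The myhz2 probe at 30198681 to 30198740 had 1.63 ± 1.77 on slide 1 (limma, adjusted p = 0.0111). On slide 2 the same probe had 1.81 ± 1.55 (limma, adjusted p = 2.70e-11). Of 23 fast muscle genes with a probe, 1 was called, against 10 of 7120 other genes (Fisher's exact p = 0.0349, adjusted p = 0.227). The prdm1 probe at chromosome 16, 7750939 to 7750998 had 0.44 ± 0.21, with adjusted p = 0.035 but less than a 2-fold change.

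In the all-probe reading, fast muscle genes made up 3 of the 6 genes that were at least 1.5-fold higher on every array. This reading was chosen after the first result was seen. Besides including dim probes it changed the signal, the normalisation and the rule, and leaving out the dim filter alone gave no calls. The 6 genes were ENSDART00000019132.41 (1.83 ± 1.02, chromosome 5, 30339786 to 30340095), myhz2 (1.67 ± 1.47), alkbh6, an AlkB family gene (1.11 ± 0.32, chromosome 5, 40612358 to 40612511), and zgc:113832 (0.94 ± 0.41), with zgc:92053 and tnni2. The last 2 encode fast troponin I and lie near each other on chromosome 25. For zgc:92053 (31791964 to 31792331) the value was 0.76 ± 0.11, with 0.72, 0.89 and 0.68 on the arrays, and for tnni2 (31797536 to 31797961) it was 0.72 ± 0.09. The windows of tnni2 and alkbh6 rested mainly on 1 probe each, at 1.94 ± 0.22 (31797902 to 31797961) and 2.17 ± 0.63 (40612452 to 40612511). Their neighbouring probes lay far lower. The fast muscle list held 3 called genes of 30, namely myhz2, zgc:92053 and tnni2, against 3 of 10235 other genes (Fisher's exact p = 4.48e-07, adjusted p = 5.82e-06). That test counts neighbouring genes as independent, although zgc:92053 and tnni2 lie near each other. Likewise myhz2, zgc:113832 and ENSDART00000019132.41 share the myosin cluster, so the p is too small. The duplicated design genes held 1 of 11, myhz2 (Fisher's exact p = 0.00641, adjusted p = 0.0417), and the other lists held 0. For the duplicated genes the adjusted p was 0.0900 without replicate 2 and 0.0693 with limma at 1.5-fold, so that result was lost in both. Adjusted over the list alone in this reading, 59 fast muscle windows were higher and 17 lower, and 14 reached 2-fold, all of 1 gene. The fast muscle list's median lay at percentile 61.9 in this reading, at 46.1 with the sign turned and at 92.6 without replicate 2, and with limma at 2-fold the list held 1 called gene (Fisher's exact, adjusted p = 0.0568).

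The opposite direction held as many windows in the all-probe reading, with 17 higher and 21 lower. Lower genes were hoxc6b (-1.13 ± 0.12, chromosome 11, 1377576 to 1378341), zgc:92099 (-0.99 ± 0.14), si:dkey-222f8.3 (-0.80 ± 0.20), acta1 (-0.77 ± 0.10), and 2 known by transcript names only, beside regions with no gene name. With the sign turned, the fast muscle list thus held 1 of 6 called genes, acta1 (Fisher's exact p = 0.0174, adjusted p = 0.226). The called acta1 windows lay within its bright run of probes. The best window of prdm1 had 0.33 ± 0.23. The best windows of pcdh8 (0.39 ± 0.13), tnnt3a (0.29 ± 0.10), fgf8 (0.27 ± 0.09), mylz2 (0.25 ± 0.09), flh (0.21 ± 0.06), vent (0.16 ± 0.08) and myod (0.15 ± 0.03) did not reach 1.5-fold.

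Negative control probes in gene deserts and from Arabidopsis thaliana stayed below the threshold. Of 769 on each slide, 38 passed the brightness filter and 0 were called with limma in the single-probe test, with median ratios of 0.04 and -0.04. Among other probes 20 of 15248 were higher on slide 1 and 9 of 12452 on slide 2 (Fisher's exact p = 1 on both). With 38 controls tested and so few calls among other probes, 0 calls were likely in any case. The comparison therefore says little about specificity, and without the fold requirement some controls passed. Pearson correlations across probes between replicate arrays were 0.35, 0.62 and 0.26 on slide 1 and 0.32, 0.69 and 0.18 on slide 2, for replicates 1 and 2, 1 and 3, and 2 and 3. Probes are not independent, so no p is given.

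The frequency of the Prdm1 consensus sequence did not differ significantly between called and matched probes. It was found in 0 of 29 higher single probes and in 3.59% of 1391 GC-matched probes (Fisher's exact p = 0.622). The 29 probes formed 17 regions counted slide by slide, and many lay in the myosin cluster, with some positions counted on both slides. They are thus not independent sites, and with so few of them a difference could hardly be seen. The GAAAG core was found in 13.8% and 12.9% (Fisher's exact p = 0.783). Among lower probes the consensus was found in 1 of 18, against 2.94% of matched probes (Fisher's exact p = 0.424).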

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

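The tests of the acta1 and myosin patterns were chosen after the results were seen, except the test of sequence shared between gene copies in the myosin cluster. The test of dependence on a single replicate was also chosen after the result, and those of abundant transcripts and of the sign patterns were stated before.

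Probes of acta1, an alpha actin gene, were bright in both channels, which the comparison used only through their ratio. In a run of 14 of 23 probes (chromosome 1, 63890204 to 63895897) the lowest median excess over probes of equal GC content, in any channel on any array, was a log2 of 2.26, and the run was delimited by that brightness. The excess was 2.26 to 2.60 in Cy3 and 2.62 to 2.91 in Cy5, against a median of 0.19 at the other acta1 probes, where single probes reached 1.54, and against -0.01 at gene desert probes, whose upper 95% point was 2.50. Extra copies of the alpha actin promoter in the GFP reporter transgene may account for it but cannot be told apart from other sources of brightness, since the run was chosen for the excess that was then measured. Shared sequence stays open too, because 28.6% of the run's probes had a near copy elsewhere on the slides. Of 3258 genes, 54 had a run as strong, acta1 itself included.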

How the results depend on the processing

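The all-probe settings (their turned sign and left-out replicates included), loess without a fold threshold and the deposited table without a filter on dim probes were chosen after the first result was seen, and the other settings were planned. The starting counts were 0 for windows higher or lower in Cy5, regions, genes and lists. Counts stayed at 0 with normexp, the LogRatio column, loess, no filter on dim probes, the filter in both channels, outlier spots kept, saturated spots left out, 5-probe windows, an intensity trend, limma treat and adjustment over both slides. An adjusted p of 0.01, a minimum of 2 windows per gene and the turned sign cannot add calls to 0, so they say nothing about stability. At an unadjusted p under 0.05 limma gave 869 higher and 1796 lower windows. The filter on dim probes limited which windows were tested, but without it 0 were called too.

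Quantile normalisation gave 8 higher and 3 lower windows, 3 regions, 1 gene and 2 lists. Centring on negative controls gave 13 higher windows, 4 regions and 3 genes. Single probes gave 29 higher, 18 lower, 17 regions and 11 genes. A reach of 500 bp gave 3 higher windows, 2 regions, 1 gene and 2 lists. A fold of 1.5 gave 9 higher, 39 lower, 5 regions and 5 genes. Without a fold threshold there were 26 higher, 118 lower, 15 regions and 15 genes. In the single-probe fit 2.63% of negative control probes were then higher, and of the other probes 729 of 27700 were, which is a like share. Array weights gave 1 higher, 5 lower, 1 region, 1 gene and 2 lists. The deposited table gave 8 higher, 4 lower, 3 regions and 3 genes, and without the filter 258 higher, 899 lower, 190 regions and 120 genes, from combined values with no test.

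The all-probe reading with a 2-fold test gave 17 higher, 5 lower, 6 regions, 3 genes and 1 list, and with 1.5-fold 48 higher, 108 lower, 13 regions, 10 genes and 1 list. The every-array rule gave 17 higher, 21 lower, 8 regions, 6 genes and 2 lists, and with offset 50 it gave 10 higher, 21 lower, 8 regions, 6 genes and 2 lists. With the sign turned it gave 21 and 17 windows, 9 regions, 6 genes and 0 lists. Loess without a fold threshold gave 4 higher, 8 lower, 2 regions and 2 genes.

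Leaving out each replicate, over the tested windows and the every-array rule together, gave 0 to 30 higher windows, 0 to 69 lower, 0 to 16 regions, 0 to 13 genes and 0 to 2 lists. For the tested windows, 20 higher and 27 lower windows were called without replicate 1, none without replicate 2, and 4 lower without replicate 3. The every-array rule gave 18 higher and 69 lower without replicate 1, 30 and 41 without replicate 2, and 22 and 66 without replicate 3.

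At least 1 window of myhz2 was called in 15 of 34 settings, of ENSDART00000019132.41 in 12 of 32, of zgc:113832 in 11 of 34, of zgc:92053 in 7 of 34 and of prdm1 in 0 of 32. Some of these settings, those with the deposited table or the every-array rule, apply no test. Several are variants of the all-probe reading and thus not independent of each other. The percentile of the myogenic regulators turned to 25.6 without the dim filter, 2.37 with the turned sign, 3.65 in the all-probe reading, 10.7 with offset 50 and 30.0 with the unfiltered table, and in the all-probe reading without replicates 1, 2 and 3 to 39.2, 0.81 and 15.7. That of the notochord and axial list turned to 0.54 with the turned sign and 44.8 in the all-probe reading, where it was 39.5 without replicate 1, 33.6 without replicate 3 and 5.55 with the turned sign. The neural crest and sensory neuron list ranged from 0, in the all-probe reading without replicate 2, to 99.8 in that reading with the sign turned, and was at 2.22 without the dim filter. The cause of these changes was not tested.

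No paired analysis was possible because each slide's test set a single ratio against 0, with no other group to pair. At the 26 shared positions, replicates of the same number on both slides correlated with r = 0.947, 0.924 and 0.987, and other pairs with 0.493 to 0.923. Restrictions to within 2 kb and 500 bp of start sites were not run, since no start sites were used here.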

Other observations

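Of the tests reported here, those of transcript-derived material, of chromatin fragments and of dependence on a single replicate were chosen after the result was seen.

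Lower windows that passed the adjusted p without a 2-fold change formed a long run at zgc:92883 (RefSeq arl1, a small GTPase of the Golgi) on chromosome 4, with a lowest log2 ratio of -0.62 ± 0.25 (n = 3). This gene and zgc:92607 were also among those with the strongest bright runs of probes on slide 1. Others lay at hpf1 (zgc:101819 in the files, a factor of PARP-dependent DNA repair, -0.58 ± 0.23), ctnna2 (si:rp71-1h10.1, an alpha catenin, -0.57 ± 0.19) and ndufab1a (zgc:92607, a mitochondrial acyl carrier protein, -0.55 ± 0.21). The heat shock protein gene dnajb1 had -0.47 ± 0.14 and taf6, of the general transcription machinery, had -0.46 ± 0.02. A window shared by the connexin genes cx39.9 and cx27.5 had -0.49 ± 0.17. Further higher windows lay at zgc:92875 (RefSeq spryd4, 0.59 ± 0.13), zgc:73111 (RefSeq wdr83os, 0.56 ± 0.24) and zgc:101661 (RefSeq haus5, a spindle assembly factor, 0.46 ± 0.11). The Prdm1 consensus was found at 1 of the 26 higher windows, against 2.42% of GC-matched probes (Fisher's exact p = 0.479).

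In the myosin cluster, probes whose translation matches a skeletal myosin heavy chain exceeded the other probes of the cluster by a median log2 of 1.24, with medians of 0.76, 0.64 and 2.54 for matching probes on replicates 1, 2 and 3, although of 27 probes at 2-fold or more 15 matched. The highest probe, at ENSDART00000019132.41 (1.99), had no match, and across probes of the cluster the ratio also correlated with brightness (r = 0.515). The matched myosin sequence was that of the motor domain, so a probe without a match may still be coding. Material derived from myosin transcripts in the Cy5 channel is a candidate explanation for part of the signal. Chromatin fragments cannot be told apart, since the 8 nearby probes without a match had a median of 0.16 but all were dim, and neither can shared sequence, since the 10 matching probes without a near copy had a median of 1.19 while probes cover 7.08% of the cluster. No biological explanation was tested, as the design has no group without Prdm1.

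Fast muscle genes among those higher on every array were tested against a pair of technical explanations. A general carry-over of abundant transcripts would raise other abundant coding sequences, but 29 probes matching actin, elongation factor 1 alpha or tropomyosin had a median log2 excess of -0.026 with a standard error of 0.03. The abundance of these transcripts in the sorted cells was not measured. Some of the probes carried names of other genes, such as rpl11 and ppp2r2b. Their median thus bears on general carry-over only as far as the matched transcripts were abundant. The 1 probe matching fast troponin I, at zgc:92053, had an excess of 1.40, while 21 probes matching skeletal myosin heavy chain outside the cluster had a median excess of 0.05 with a standard error of 0.08, and the 4 of them above a ratio of 0.5 all lay on contig NA468. These 21 include probes named myh6, and the match did not separate fast muscle genes from other myosin heavy chain genes. Their median thus says little about fast muscle transcripts. Dependence of the share of fast muscle genes on a single replicate could not be decided, since genes higher on all 3 arrays also pass on any pair of them. With replicates 1, 2 and 3 left out the list held 3 genes against 4, 10 and 3 other genes (Fisher's exact, adjusted p = 1.01e-05, 8.19e-05 and 5.80e-06). The 3 were fixed by their choice, and only a far larger number of other genes could have raised the adjusted p. Carry-over, including one limited to some fast muscle transcripts, may remain, given the difference of 1.24 in the myosin cluster, and binding at these genes was not tested.

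With 3 arrays there are 4 sign patterns, so no share under 0.05 is possible. On slide 1 the windows past adjusted p alone numbered 136, the highest other pattern, with replicate 1 turned, gave 22, and no other pattern reached the real value. On slide 2 they numbered 8, and 2 patterns reached the real value, the real one included. The highest other pattern, again with replicate 1 turned, gave 27. That count is several times the real one and points to a structure of the arrays that was not resolved. At the 2-fold threshold the real value was 0 on both slides, and the pattern with replicate 1 turned gave 5 on slide 1 and 2 on slide 2. In the all-probe reading the real value was 38, the highest other was 0, and no other pattern reached the real value.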
